A study of Danio rerio with 6 samples.

How the data were processed

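RNA was measured on 6 two-colour Agilent arrays of zebrafish embryos, 3 for the line hi2217 and 3 for the line hi1520. Per the labels, each array carried RNA of a pool of 30 to 50 mutant embryos labelled with Cy5 and RNA of a pool of their wild-type siblings labelled with Cy3, with 0.5 µg of total RNA amplified and 6 µg of the amplified RNA coupled to dye. Both lines came from crosses of heterozygous adults, and the 3 arrays of a line were biological replicates per the labels. No array carried the dyes the other way round, so an effect of the dyes on a single probe cannot be told apart from an effect of genotype within a line. Such an effect cancels in the difference between the lines where it is equal on all arrays. Arrays were assigned to lines and replicate numbers by their titles.

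The deposited scanner files hold spot intensity on a linear scale for both dyes, as foreground mean and local background median, per the file headers. They were made with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited files also hold the software's processed intensity, and its log10 ratio of Cy5 over Cy3, after background subtraction, spatial detrending and dye normalization, per the file headers. The deposited value table is a score: set against the scanner files, most cells are a signed fold change of Cy5 over Cy3, written as the ratio where it is at least 1 and otherwise as minus its inverse. The sign of its cells was that of the scanner ratio in 100% of cells of each array. Its column medians were -0.104, -0.108 and 1.02 for hi2217 replicates 1, 2 and 3, and -0.137, -1.00 and -1.00 for hi1520 replicates 4, 5 and 6. Between 11.5% and 13.3% of the cells of an array had a size below 1 and are not such a fold change. The medians of -0.104, -0.108 and -0.137 are below 1 in size as well, so they do not give a typical fold change. Of the other cells, 99.93% to 99.96% equalled it within 1.5e-05.

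The files name 43370 probes of 60 bases other than controls, with 42152 distinct sequences. Gene name, systematic name and probe name were identical for every probe, the number of probes paired with a gene name was 0, and the genomic position was listed as unmapped. The reference tables used here hold no probe sequences. Tests of the gene lists and cell type markers fixed before the data were examined, the check of the targeted genes and the naming of genes by symbol were therefore not run, and probes are given by ID and sequence. The rule for naming was the highest and the lowest log2 fold changes among probes past the threshold with the same sign on all 3 arrays of a line, or with no overlap between the lines for the difference. It was reduced to 2 probes on each side of each comparison because no symbols were paired with the IDs.

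Background was corrected with normexp (offset 50) on foreground mean and background median, and log2 ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots flagged as outliers by the scanner software were left out, and saturated spots were kept. A probe was kept if it was well above background in at least 1 channel on at least 3 of the 6 arrays, which left 41123 probes. No probe ID occurred more than once, so each ID was tested as 1 probe, including IDs that share a sequence. The log2 ratios were fitted with lmFit and eBayes with 1 coefficient per line, and the difference was hi2217 minus hi1520. P-values were adjusted by the Benjamini-Hochberg method over the probes kept, and probes with an adjusted p under 0.05 were called. Overlaps were tested with Fisher's exact test. Fold changes are mutant over sibling.

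Median foreground signal over local background per array was 57.4 to 78.4 in the Cy5 channel and 39.5 to 59.8 in the Cy3 channel. The number of arrays limits the precision. The fit was tested on simulated signals with 200 probes changed per line and equal spread in both lines. For the hi2217 comparison 89.0% of changes of size 1 (log2) and 97.0% of size 2 were recovered among 41123 probes, with 13 other probes called. For hi1520 the shares were 95.0% and 99.0%, with 10 other probes called, and for the difference they were 64.0% and 96.0%, with 16 other probes called. In the data the median SD between arrays was 0.11 in hi2217 and 0.24 in hi1520, so these shares do not rank the lines.

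The alternatives were the scanner software's processed signals, no background subtraction, median centring, Aquantile scaling between arrays, no filter and a stricter filter, the value table with cells below 1 in size left out, each line alone, array weights, trend and robust empirical Bayes, a fold threshold, the slide as a block, and leaving out each array. Aquantile scaling acts on the mean signal and leaves the log2 ratios as they are, so its calls could not differ from those of the main fit. Chosen after the data were seen were the averaging of identical sequences, the removal of each array's trend on GC content, and the processed signals without hi2217 replicate 3. Scan records placed the arrays on 3 slides. Slide 1 held hi2217 replicates 1 and 2, slide 2 held hi2217 replicate 3 and hi1520 replicate 4, and slide 3 held hi1520 replicates 5 and 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.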

Results

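Gene expression was compared between mutant zebrafish embryos and their wild-type siblings in 2 lines, hi2217 and hi1520, each carrying a retroviral insertion. The insertion of hi2217 lies in the locus of Hai1, an inhibitor of membrane-bound serine proteases, and that of hi1520 lies in the locus of Clint1, an adaptor protein of clathrin-coated vesicles. The title of the series concerns inflammation in the absence of Hai1. Each line was measured on 3 arrays, each with its own pool of mutants in Cy5 and of siblings in Cy3. The share of probes well above background ranged from 87.9% to 94.4% in the Cy5 channel and from 89.2% to 94.6% in the Cy3 channel. Saturation touched at most 7 probes per array, all in the Cy5 channel.

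Log2 ratios of the 3 hi2217 arrays correlated with r between 0.70 and 0.80 across probes, which are not independent replicates. Those of the 3 hi1520 arrays correlated with r between 0.29 and 0.57. The arrays did not group by line: hi1520 replicate 5 correlated at 0.70, 0.63 and 0.67 with hi2217 replicates 1, 2 and 3, and at 0.57 and 0.45 with hi1520 replicates 4 and 6. The median SD between arrays of a probe was 0.11 in hi2217 and 0.24 in hi1520 (n = 3 each). Within single arrays, probes of identical sequence differed by an SD of 0.095 to 0.16, with the most repeated sequence left out. The 172 copies of that sequence had an SD of 0.17 to 0.31. The hi2217 arrays were thus closer to each other than the hi1520 arrays were, and the joint fit gave both lines 1 estimate of the spread, which was lenient on hi1520 and strict on hi2217. The counts of calls do not rank the lines: 1079 in hi2217 against 2485 in hi1520 in the joint fit became 5318 against 678 with each line fitted alone.

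The first comparison asked which transcripts differ between embryos with the Hai1 insertion and their siblings. Of 41123 probes, 911 were higher and 168 lower in hi2217 mutants (limma, adjusted p under 0.05). The rises were also larger than the falls. At least 2-fold changes numbered 559 among the rises and 27 among the falls, and at least 4-fold changes 85 and 2. The median log2 fold change was 1.28 for the probes that rose and -0.65 for those that fell. Among the 911 were 171 of 172 probe IDs that share 1 sequence, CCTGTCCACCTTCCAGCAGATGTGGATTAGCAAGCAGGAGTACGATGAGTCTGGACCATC, with mean log2 ratios of 1.72, 1.68 and 1.65 on the 3 arrays. With identical sequences averaged, 620 sequences were higher and 126 lower. The counts by fold and the medians above are by probe ID, include these copies and were not recomputed by sequence.

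The largest rise in hi2217 was that of probe A_15_P114154 (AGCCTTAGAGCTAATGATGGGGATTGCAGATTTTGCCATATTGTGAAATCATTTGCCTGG), with a log2 fold change of 3.88 (SE 0.20, limma adjusted p = 0.000177), or 14.7-fold. Its log2 ratio was 3.53, 3.65 and 4.45 on the 3 arrays. Probe LOL01069 (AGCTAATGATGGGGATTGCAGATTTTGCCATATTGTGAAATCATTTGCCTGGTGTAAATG) shares at least 30 bases with it and rose by 3.74 (SE 0.18, limma adjusted p = 0.000171). With the deposited value table LOL01069 rose by 2.86 but was not called (SE 0.71, limma adjusted p = 0.194). The scanner software's processed signals gave 3.97 (SE 0.26, limma adjusted p = 0.00113). With the value table only flagged spots and cells below 1 in size were left out, so other cells unlike the scanner ratio remained. The deepest falls were those of A_15_P105559 (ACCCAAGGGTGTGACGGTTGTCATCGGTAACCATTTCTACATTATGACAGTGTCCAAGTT), at -2.37 (SE 0.24, limma adjusted p = 0.00252), and of LOLS02339 (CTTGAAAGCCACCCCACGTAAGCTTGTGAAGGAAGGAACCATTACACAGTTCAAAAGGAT), at -2.22 (SE 0.20, limma adjusted p = 0.00140). In hi1520 these 2 probes were at -0.55 and -0.44 and were not called, and the difference between the lines was not called for either (limma adjusted p = 0.280 and 0.186). Their log2 signal in the siblings was 11.7 and 11.2 in hi2217 against 9.04 and 9.01 in hi1520, so the siblings differed in level. The genomic position of these and all other probes is not given in the files.

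The count of hi2217 calls was 5318 (3159 higher, 2159 lower) with the 3 hi2217 arrays fitted alone, 6582 (3847 higher, 2735 lower) with array weights, 547 (517 higher, 30 lower) with the scanner software's processed signals, and 422 to 475 when any 1 of the hi2217 arrays was left out. Without replicate 1, 2 or 3 the falls numbered 13, 32 and 14 and the rises 462, 435 and 408. It was 2232 without hi1520 replicate 4, the array with the widest log2 ratios, and the falls numbered 612, 88 and 313 without hi1520 replicate 4, 5 or 6.

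The second comparison asked the same of the Clint1 insertion. In hi1520 mutants 1983 probes were higher and 502 lower (limma, adjusted p under 0.05), of which 840 rises and 23 falls were at least 2-fold and 137 and 5 at least 4-fold. The median log2 fold change was 0.88 for the rises and -0.51 for the falls. Among the rises were 171 of the 172 IDs of the repeated sequence, at mean log2 ratios of 1.93, 1.69 and 1.76. With identical sequences averaged, 1604 sequences were higher and 422 lower. Here too the counts by fold and the medians are by probe ID and include these copies. Of the rises, 29 belonged to probes that were not well above background in the siblings on any of the 3 arrays, against 3 in hi2217.

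Probe LOLS00802 (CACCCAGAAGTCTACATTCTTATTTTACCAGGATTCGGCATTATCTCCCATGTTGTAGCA) rose most in hi1520, with a log2 fold change of 3.36 (SE 0.14, limma adjusted p = 0.000101), and also rose in hi2217, by 2.69 (SE 0.14). Its Cy5 spot was saturated on 1 of the 3 arrays of each line, where the mutant signal is a lower limit, so its rank and folds are uncertain. It was followed by A_15_P118692 (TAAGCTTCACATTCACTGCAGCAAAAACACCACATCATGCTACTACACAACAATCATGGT), at 3.27 (SE 0.22, limma adjusted p = 0.000244) in hi1520 and 1.19 in hi2217. The difference between the lines was not called for either probe (limma adjusted p = 0.545 and 0.169). The deepest falls in hi1520 were those of LOLS03622 (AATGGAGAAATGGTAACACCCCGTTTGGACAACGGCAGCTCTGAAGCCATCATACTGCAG), at -2.55 (SE 0.097, limma adjusted p = 0.000101), and A_15_P106475 (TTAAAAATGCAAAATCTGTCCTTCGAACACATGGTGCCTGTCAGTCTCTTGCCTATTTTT), at -2.45 (SE 0.12, limma adjusted p = 0.000117). In hi2217 the same probes were at 0.38 and -0.04 and were not called. The SEs and p-values above are of the joint fit, which was lenient on hi1520. With the hi1520 arrays fitted alone, the SEs in hi1520 were 0.18 for LOLS00802, 0.26 for A_15_P118692, 0.13 for LOLS03622 and 0.16 for A_15_P106475. All of these probes were still called there (limma adjusted p from 0.00817 to 0.0106). All named probes were well above background in both channels on all 6 arrays.

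The count of hi1520 calls was 678 (661 higher, 17 lower) with the 3 hi1520 arrays fitted alone, all of them among the 2485 of the joint fit, and 917 (840 higher, 77 lower) with the processed signals. It was 1249 to 1399 when any 1 of the hi2217 arrays was left out, with 121, 92 and 90 falls and 1278, 1157 and 1190 rises without replicate 1, 2 or 3. Falls numbered 262 without hi1520 replicate 4 and 273 without hi1520 replicate 6.

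The changes of the 2 lines were then compared with each other. Across the 41123 probes the log2 fold changes correlated with r = 0.69. Of the 911 rises in hi2217, 753 were also called as rises in hi1520, against 43.9 for independent lists (odds ratio 151, Fisher's exact test over probes, which are not independent of each other). The shared rises numbered 429, 415 and 390 without hi2217 replicate 1, 2 or 3, 407 with the processed signals, 327 with the value table and 1259 with median centring. Of the 168 falls, 48 were shared, against 2.05 (odds ratio 35.7, Fisher's exact p = 1.19e-51). The shared falls numbered 2, 10 and 4 without hi2217 replicate 1, 2 or 3, 14 without hi1520 replicate 5, 8 with the processed signals, 4 with the value table and 75 with the GC trend removed, a setting chosen after the data were seen. Only 3 probes were called in opposite directions. The lines shared no RNA, but the mutant was in Cy5 on every array, so a dye effect of single probes would also be shared. Both lists also came from the joint fit with 1 spread per probe. Calls would therefore coincide more often than in independent lists even without shared changes. Counted by distinct sequence, 492 rises and 38 falls were shared. The expected counts and odds ratios above are by probe ID, with copies of 1 sequence counted separately, and were not recomputed by sequence.

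**Figure D1:**
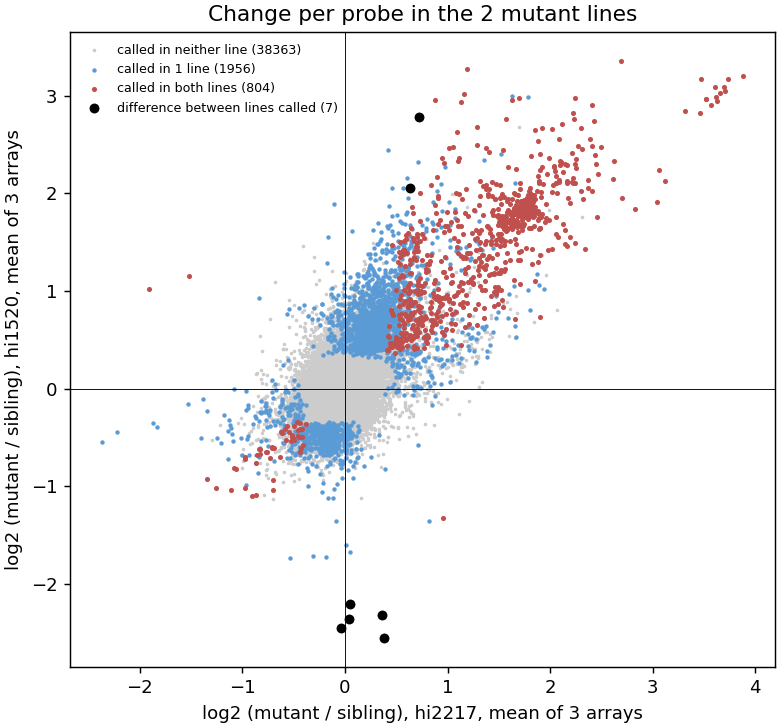
Each point is 1 probe, with its mean log2 ratio of mutant over sibling over 3 arrays in hi2217 on the x axis and in hi1520 on the y axis. The 804 probes called in both lines lie mostly along a rising diagonal, and the 7 probes with a called difference lie away from it.

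The difference between the lines was called for 7 probes, 5 higher and 2 lower in hi2217 than in hi1520 (limma, adjusted p under 0.05), and 2994 probes had an unadjusted p under 0.05. LOLS03622 differed by 2.93 (SE 0.14, limma adjusted p = 0.00548) and LOLS09151 (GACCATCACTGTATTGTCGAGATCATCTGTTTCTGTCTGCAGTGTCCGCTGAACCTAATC) by 2.68 (SE 0.18, limma adjusted p = 0.0190). All 5 of the higher probes fell in hi1520, with log2 fold changes from -2.55 to -2.21, and were at -0.04 to 0.38 in hi2217 with no call. The 2 lower probes rose in both lines and more in hi1520. A_15_P116930 (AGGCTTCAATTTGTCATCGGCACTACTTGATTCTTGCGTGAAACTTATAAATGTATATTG) rose by 0.73 in hi2217 and 2.78 in hi1520, a difference of -2.06 (SE 0.12, limma adjusted p = 0.0145). A_15_P116732 (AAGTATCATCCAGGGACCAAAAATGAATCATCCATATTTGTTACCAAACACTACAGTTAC) rose by 0.63 and 2.06, a difference of -1.43 (SE 0.12, limma adjusted p = 0.0482).

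**Figure D2:**
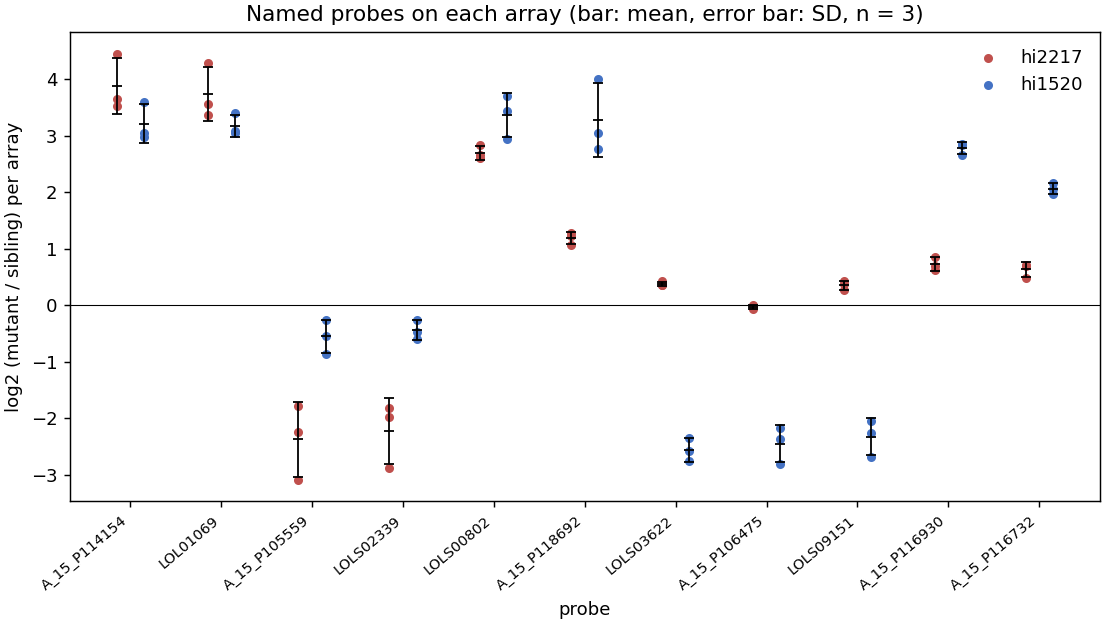
Log2 ratio of mutant over sibling on the y axis for each named probe on the x axis, with 1 point per array, red for hi2217 and blue for hi1520, bars at the mean and error bars of 1 SD (n = 3). LOLS03622, A_15_P106475 and LOLS09151 lie below -2 on each hi1520 array and near 0 on each hi2217 array.

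The 2 lines met only on slide 2, with 1 array each, and the other slides each held 1 line. Within slide 2 LOLS03622 differed by 3.12, LOLS09151 by 3.05, A_15_P116930 by -1.98 and A_15_P116732 by -1.25. The fit with the slide as a fixed block gave the same estimates, since it compares the lines through this pair alone. A lack of calls in that fit therefore cannot tell whether the differences belong to the lines or to the slides. With the slide as a fixed block no difference was called (0 probes by limma, 6352 at an unadjusted p under 0.05), and the smallest adjusted p of these probes was 0.128. No difference was called either without any 1 of the hi2217 arrays or without hi1520 replicate 5, while 3 probes were called without hi1520 replicate 6 and 15 without hi1520 replicate 4.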

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

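The tests of the scanner software's ratios, of the value table, of the dye effect and of repeated sequences were chosen after the results were seen. The GC correction was chosen after the data were seen, and its prediction was written before its result.

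The difference between the lines passed the threshold for 7 probes, by a direct test of hi2217 minus hi1520. LOLS03622 (2.93), LOLS09151 (2.68) and A_15_P106475 (2.41) were lower in hi1520 mutants than in their siblings and were not called in hi2217. A_15_P116930 (-2.06) and A_15_P116732 (-1.43) rose in both lines and more in hi1520. The other 2 probes differed by 2.26 and 2.39. Of the 10 splits of the 6 arrays into 3 and 3, the real one, 1 of 10, called 7 probes and the highest of the others called 0, which is too few splits for a share under 0.05. For each line, 4 patterns of signs of its 3 arrays were too few as well: 1 pattern, the real one, called 1079 probes in hi2217 and 2485 in hi1520, and the highest of the others called 0.

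Rises outnumbered falls in both lines, and 753 of the 911 rises in hi2217 and of the 1983 in hi1520 were shared. In hi2217 the imbalance was smaller with array weights (3847 rises, 2735 falls) and with the line alone (3159 and 2159). In the joint fit, repeated sequences do not account for the imbalance, since falls were at most 20.8% of the called sequences with identical sequences averaged. With the GC trend removed, 96.3% of the shared rises stayed shared rises. Rises still outnumbered falls there, with 1044 against 258 in hi2217 and 2283 against 676 in hi1520. A GC trend therefore does not account for the imbalance or the sharing. A dye effect of single probes may remain and, with no array of swapped dyes, cannot be told apart from a change common to both mutants, which is also left open. The share of shared calls with a tested difference between the lines, 0.25%, decides nothing, because that test called 7 of 41123 probes in all.

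The scanner software's log2 ratios of hi2217 replicate 3 had an SD of 0.76, against 0.38 and 0.33 on the other hi2217 arrays. The file statistics give a multiplicative detrending fit of 0.304 for the green channel of this array and 0 for the red. On the 2 other arrays that were detrended both channels were. A candidate explanation is that a spatial correction of 1 channel alone was carried into the ratio: the 172 copies of 1 sequence had an SD 3.84 times as large in the processed as in the loess ratio here, and at most 1.74 times elsewhere. A pool of embryos that truly differed would leave copies of 1 sequence on an array alike. Their spread thus argues against such a pool as the cause of the wide processed ratios. The loess ratios of this array correlated with the other hi2217 arrays at r = 0.70 or more. That cannot tell whether the pool differed, because hi1520 replicate 5, of the other line, correlated with the hi2217 arrays at 0.63 to 0.70.

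The cells of the value table below 1 in size were also examined, and no biological explanation was tested. If the last decimals were lost where they were 0, such a cell would equal the remaining digits moved behind the point, and 98.9% of them did, within 1.5e-05. A loss of trailing zeros when the table was written is therefore a candidate explanation of these cells.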

How the results depend on the processing

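Of the alternative settings, the averaged sequences, the GC trend and the processed signals of 5 arrays were chosen after the data were seen. The lines share no replicate numbers, so the replicate number was not used as a block. The planned gene list, targeted gene and gene symbol alternatives were not run, since no gene names were paired with the probes. Median signal over background was at least 39.5 on every array and channel. In the ranges below with 1 array left out, some counts moved by 1.5 times or less. These include the hi1520 calls (1989 to 2577) and the shared calls (636 to 1148) without 1 hi1520 array. The other counts of calls moved by over 1.5 times as follows, and the cause was not tested. For hi2217 (1079), they were 547 with processed signals, 1920 with median centring, 459 with the value table, 5318 with the line alone, 6582 with array weights, 602 with trend and robust empirical Bayes, 586 with a log2 fold change of at least 1, 356 with processed signals of 5 arrays, and 422 to 2232 with 1 array left out. For hi1520 (2485), in the same settings, they were 917 with processed signals, 728 with the value table, 678 with the line alone, 1196 with trend and robust empirical Bayes, 863 with the fold threshold, 975 with processed signals of 5 arrays, and 1249 to 2577 with 1 array left out. For the shared calls (801), they were 415 with processed signals, 1308 with median centring, 331 with the value table, 530 with identical sequences averaged, 325 with processed signals of 5 arrays, and 394 to 1148 with 1 array left out. For the difference (7), limma called 1 probe with processed signals, 14 with median centring, 14 with the stricter filter, 54 with array weights, 11 with the GC trend removed, and 0 to 15 with 1 array left out. It called 0 with the value table, with trend and robust empirical Bayes, with the slide as a fixed block and with processed signals of 5 arrays, where 2007, 2732, 6352 and 1682 probes had an unadjusted p under 0.05. Leaving out any hi2217 array or hi1520 replicate 5 also gave 0 (1575 to 4932 at an unadjusted p under 0.05). The split of 5 higher and 2 lower probes became 14 and 40 with array weights and 7 and 7 with median centring. It was 8 and 6 with the stricter filter, 6 and 5 with the GC trend removed, and 6 and 9 without hi1520 replicate 4. Of 240 values of named probes under the alternatives, 200 kept direction and call, 40 kept direction without the call, and 0 reversed.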

Other observations

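Probes that share at least 30 bases measure nearly the same stretch of a transcript and were compared as a check of single probes. Over 2445 such pairs the log2 fold changes correlated with r = 0.91 in hi2217 and 0.92 in hi1520. Of the pairs with a change over 1 in size, 100% of 136 had the same sign in hi2217 and 99.3% of 140 in hi1520. A dye effect of the shared bases would be common to both probes of a pair, so these values do not check for it.

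The correlation of log2 ratio with GC content across probes was -0.31 on hi1520 replicate 4 and 0.17 on hi1520 replicate 6, the 2 arrays with the widest log2 ratios (SD 0.58 and 0.48). On the other 4 arrays it lay between -0.14 and 0.14.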
